A study of Sus scrofa with 8 samples.

How the data were processed

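RNA was sequenced from cultured primary cells of the skeletal muscle of pigs (strain LYD as the labels give it). The 8 libraries were undifferentiated or differentiated cells of females or males, 2 libraries in each of 4 groups. Per the labels, the libraries were made with a stranded total RNA kit for low input and read as 100-bp paired ends, while the molecule is given as polyA RNA. The protocol calls the cells MuSCs.

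The deposited table holds FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, for 25285 genes with Ensembl pig identifiers. Per the submitters' processing notes, the values came from cutadapt 1.6, TopHat2 2.0.12.1 and Cufflinks 2.2.1 on the genome build Sscrofa10.2. The settings of those tools and the total used for scaling are not stated. A column with the number of libraries per gene was not used, because it differed from the number of libraries above 0 for 189 genes. Of the 25285 genes, 16274 carried a symbol in the table, 1841 were named from an Ensembl identifier table and 7170 stayed without a symbol. The identifier table held 11791 of the identifiers. Symbols were matched exactly, and where several genes carried 1 symbol the one with the highest mean stood for it in the gene lists.

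Whole read counts were not recovered from the FPKM values, so no count-based test was used and the depth in reads is unknown. A relative depth was estimated from 4223 genes with low values, in which the commonest ratio between a pair of libraries was taken as 1 fragment against 1 fragment. The 28 pairs were described by 1 depth per library with a largest misfit of 0.0429 and a median misfit of 0.0066 on the log2 scale. The table held values of up to 8879310000 FPKM, and 214 of the 218 genes with a value above 100000 FPKM spanned under 300 bp. Such values were kept in the main analysis and left out in an added alternative, which left 12603 tested genes.

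Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 8 libraries were tested, which gave 12963 genes, 10480 of them with a symbol. R 4.3.3 with limma 3.58.1 was used (lmFit, contrasts.fit and eBayes with a mean-variance trend), with 1 mean per group and no block, 4 residual and 2.09 prior degrees of freedom. The contrasts were differentiated against undifferentiated cells averaged over the sexes and within each sex, female against male averaged over the states and within each state, and the difference of the differentiation effect between the sexes. Two-sided p-values were adjusted over all tested genes by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was called. "Rose" and "fell" are used for genes that passed this test, and ± gives the SD of FPKM. The p-values measure only the spread between these libraries, since no label says that replicates came from separate animals.

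The gene lists, the contrasts, the tests of genes, the rule for named genes and the alternatives other than that on short genes were fixed before the data were examined. List tests were planned only for the states averaged over the sexes and for the sexes averaged over the states. Those within a sex or a state and for the difference of the effect were outside that plan, as were their repeats with libraries left out. The 29 gene lists covered myogenic regulators, satellite cells and quiescence, the Notch pathway, myoblast fusion, the sarcomere, excitation-contraction coupling, the neuromuscular junction, the dystrophin complex and costamere, the cell cycle, cell cycle exit, glycolysis and creatine kinase, mitochondrial respiration, mitochondrially encoded genes, the IGF and growth factor axis, the TGF-beta, BMP and myostatin axis, extracellular matrix and fibroblasts, smooth muscle and pericytes, adipogenic genes, endothelial, immune and Schwann cell markers, cholesterol synthesis, the interferon response, heat shock and unfolded protein, serum and immediate early genes, inflammatory cytokines, sex steroid genes, Y-linked genes, and X-linked partners with XIST. The lists with at least 5 tested members, 24 of the 29, were tested with limma's camera at its preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and limma's fry, for 1 direction and for either direction, were alternatives.

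Genes were named by rule. For the states these were the 10 symbols with the largest rise and the 10 with the largest fall among genes past the threshold with the same sign in both sexes and no overlap between the 4 libraries of each state. Each list added its 2 most risen and 2 most fallen members. For every other contrast the 5 symbols with the largest change in each direction were taken. All tested members of the sex-linked lists and a set of muscle and cell cycle genes were named as checks of the labels. Genes without a symbol, gene families and other genes named outside this rule were chosen after their values were seen.

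The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, median-ratio scaling, no mean-variance trend, library weights, replicate number as a fixed block, sex and replicate number together as a random or a fixed block, only the libraries of the groups compared, and each library left out in turn. The test was checked on simulated data with 12963 genes, of which 50 were changed at each fold. These were drawn from genes of at least 300 bp with a mean log2 value above 1.5. The real comparison of states called 6476 genes, so its adjusted threshold was less strict than in the simulation. The simulated shares for the states therefore do not carry over to it. For the states averaged over the sexes, 18% of the genes changed 1.5-fold, 62% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold were called, with 4 false calls. For 1 sex alone, 32% at 2-fold and 82% at 4-fold were called. For the sexes averaged over the states, 40% at 2-fold and 94% at 4-fold were called. For the difference of the effect between the sexes, 0% at 2-fold and 64% at 4-fold were called.

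Mitochondrially encoded genes could not be tested because none was found in the table under the symbols used. PAX7, MYF5, MYH2 and MYH8 were not found under their symbols and are not analysed here. Results of some single genes within the lists are not reported here.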

Results

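Gene expression was measured by RNA sequencing in primary skeletal muscle cells of pigs, grown in culture and collected undifferentiated or differentiated. Each state held 2 libraries from females and 2 from males. Values are FPKM as deposited, with positions on Sscrofa10.2. The depth in reads is unknown. Relative to differentiated female replicate 1, set to 1, the estimated depth of undifferentiated libraries was 2.25 and 2.23 in females and 1.97 and 1.66 in males. The other differentiated libraries had 1.59 in female replicate 2, and 1.62 and 1.26 in males. Between 11940 and 12167 genes reached 1 FPKM in the undifferentiated libraries and between 12630 and 13074 in the differentiated ones. Across the 12603 tested genes of at least 300 bp, Pearson's r of log2 values was 0.931 to 0.959 within groups, 0.923 to 0.965 between the sexes of 1 state and 0.740 to 0.805 between states, where genes are not independent replicates. The component of largest variance held 70.3% of the variance and the next 7.55%.

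The comparison of differentiated with undifferentiated cells, averaged over the sexes, asked which genes changed with the state of the cultures. ACTA1 (skeletal muscle actin, ENSSSCG00000010190, chromosome 14, 65236451 to 65239189) rose from 0.650 ± 0.420 to 4520 ± 638 FPKM (SD, n = 4 libraries per state, log2 fold change 11.44 ± 0.172 SE, limma adjusted p = 1.3e-06). MYH3 (embryonic myosin heavy chain, ENSSSCG00000018007, chromosome 12, 58110959 to 58132945) rose from 4.25 ± 3.11 to 4410 ± 699 FPKM (n = 4, log2 9.86 ± 0.295 SE, limma adjusted p = 8.45e-06). CCND1 (cyclin D1, ENSSSCG00000012873, chromosome 2, 2342270 to 2343202) fell from 902 ± 133 to 38.8 ± 10.6 FPKM (n = 4, log2 -4.53 ± 0.212 SE, limma adjusted p = 4.05e-05). CKM (muscle creatine kinase, ENSSSCG00000025268, scaffold GL896419.1) was listed at 0 in 3 undifferentiated libraries and at 0.122 FPKM in the remaining one, and was at 483 ± 129 FPKM in differentiated cells (limma adjusted p = 1.3e-06).

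Of 12963 tested genes, 2339 rose and 4137 fell (limma, Benjamini-Hochberg adjusted), so that 63.9% of the called genes fell. The median log2 fold change of all tested genes was -0.18. Median-ratio scaling raised that median by 0.185 and gave 3128 genes that rose and 3008 that fell, with all 2339 rises and 3008 of the falls kept and 0 genes called the other way. All 4 differentiated libraries lay above all 4 undifferentiated ones for 2215 genes and below them for 3914. Such genes made 47.3% of those tested, where chance gives 2.86%.

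HUMMLC2B, a myosin light chain by the table's description, was at 4.18, 8.78, 0 and 3.20 FPKM in undifferentiated cells and rose to 5119 ± 1240 FPKM (n = 4, limma adjusted p = 3.71e-05). MYL4, an atrial and embryonic myosin light chain, rose to 2171 ± 656 FPKM (n = 4, log2 9.99, limma adjusted p = 6.52e-06). MYL1, a fast myosin light chain, rose from 5.06 ± 0.608 to 2956 ± 625 FPKM (n = 4, log2 8.91, limma adjusted p = 1.3e-06). TNNC2, fast troponin C, was listed at 0 in 1 undifferentiated library and reached at most 0.784 FPKM in the others, against 1143 ± 347 FPKM in differentiated cells (n = 4, limma adjusted p = 4.79e-06). MYBPH, a myosin-binding protein, rose from 2.69 ± 2.10 to 2035 ± 233 FPKM (n = 4, limma adjusted p = 1.58e-05). KLHL31, a kelch protein of muscle, was at 0, 0.0989, 0.222 and 0.266 FPKM and rose to 352 ± 84.6 FPKM (n = 4, limma adjusted p = 2.21e-06). SNORA42, a small RNA gene of 137 bp, was listed at 0 in all undifferentiated libraries and at 557800, 41640, 585800 and 285100 FPKM in the differentiated ones.

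S100A4, a calcium-binding protein of motile cells, fell from 1568 ± 349 to 56.5 ± 15.3 FPKM (n = 4, log2 -4.78, limma adjusted p = 7.71e-06). Its neighbour S100A5 was at 23.0 ± 8.58 FPKM in undifferentiated cells and listed at 0 in all 4 differentiated libraries (limma adjusted p = 9.9e-05). HMGA2, a chromatin protein of proliferating cells, fell from 94.4 ± 33.6 to 8.26 ± 7.39 FPKM (n = 4, log2 -3.75, limma adjusted p = 0.000539). DUSP5, a phosphatase acting on ERK, fell from 40.6 ± 7.21 to 1.87 ± 0.729 FPKM (n = 4, log2 -3.88, limma adjusted p = 5.3e-05). ITGA3, an integrin, fell from 130 ± 46.7 to 9.12 ± 4.21 FPKM (n = 4, limma adjusted p = 0.000114). CLDN6, a claudin, fell from 82.1 ± 30.1 to 3.74 ± 0.539 FPKM (n = 4, log2 -4.07, limma adjusted p = 0.000119). ESM1 fell from 98.2 ± 34.2 FPKM to 0, 0.511, 4.88 and 6.94 FPKM (limma adjusted p = 0.000112). DOK6 was at 19.2, 75.4, 74.7 and 140 FPKM in undifferentiated cells, and in differentiated cells at 14.0 FPKM in male replicate 1 and listed at 0 elsewhere (limma adjusted p = 0.00526). VGF, which spans 249 bp, was at 147 ± 62.2 FPKM in undifferentiated cells (n = 4) and at 0, 16.2, 34.3 and 6.81 FPKM in differentiated ones (limma adjusted p = 0.0156). The VGF call ended without undifferentiated female replicate 1 (adjusted p = 0.0606), undifferentiated male replicate 1 (0.0518), undifferentiated male replicate 2 (0.0522) or differentiated male replicate 2 (0.0555).

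**Figure D1:**
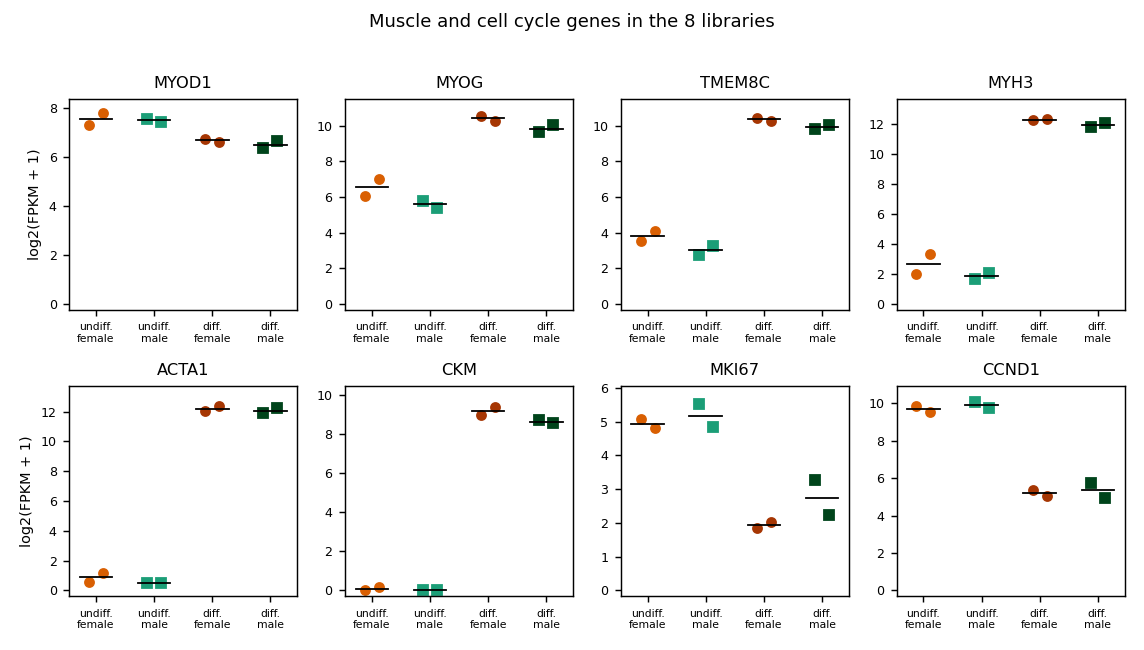
Points show log2(FPKM + 1) of MYOD1, MYOG, TMEM8C, MYH3, ACTA1, CKM, MKI67 and CCND1 in the 8 libraries, by state and sex, and bars the mean of each group of 2. ACTA1 lay between 0.417 and 1.28 FPKM in undifferentiated and between 3763 and 5179 FPKM in differentiated libraries.

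The regulators of the muscle program moved in both directions. Of 11 tested myogenic regulators, 6 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone. MEF2C rose from 7.14 ± 2.09 to 1190 ± 142 FPKM (n = 4, log2 7.22, limma adjusted p = 6.64e-06). MYOG, the myogenin that starts terminal differentiation, rose from 72.4 ± 39.5 to 1152 ± 307 FPKM (n = 4, log2 4.07, limma adjusted p = 0.000106). MYOD1 fell from 184 ± 28 to 94.8 ± 10.4 FPKM (n = 4, log2 -0.94, limma adjusted p = 0.00239). The list as a whole was not called by camera (adjusted p = 0.152, and adjusted p = 0.565 with an estimated correlation). Of 11 satellite cell and quiescence genes, 3 rose and 6 fell, also when adjusted over the list alone, and 2 did not pass (camera adjusted p = 0.473, adjusted p = 0.741 with an estimated correlation). MEGF10 and NCAM1 rose with log2 fold changes of 1.80 and 1.78, and SDC4 (log2 -2.58) and FGFR4 (log2 -1.81) fell. In the Notch pathway 2 of 11 members rose and 6 fell, also when adjusted over the list alone, and 3 did not pass (camera adjusted p = 0.473, adjusted p = 0.724 with an estimated correlation). NOTCH3 (log2 1.86) and HES6 (log2 1.15) rose, while LFNG (log2 -1.90) and NOTCH2 (log2 -1.58) fell. Among 11 fusion genes 5 rose, 3 fell and 3 did not pass, 5 and 4 when adjusted over the list alone (camera adjusted p = 0.0972, adjusted p = 0.391 with an estimated correlation). Under median-ratio scaling, and without differentiated male replicate 1, 1 of the 3 falls was left. TMEM8C, the fusion factor myomaker, rose from between 5.79 and 15.8 FPKM to 1160 ± 214 FPKM (n = 4, log2 6.76, limma adjusted p = 5.57e-06) and ITGB1BP2 with a log2 fold change of 4.82. MYOF fell (log2 -1.41). The call of CDON (log2 -0.74, adjusted p = 0.0289) ended under median-ratio scaling (adjusted p = 0.0603), quantile normalization (0.0522) and without any 1 of 6 of the libraries (adjusted p = 0.0582 to 0.0931).

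Of 40 sarcomere genes, 39 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 5.63 (camera adjusted p = 5.71e-28, adjusted p = 0.285 with an estimated correlation). The member that fell was TPM3, a tropomyosin also made outside muscle, from 190 ± 18.7 to 73.1 ± 7.33 FPKM (n = 4, log2 -1.37, limma adjusted p = 0.00029). MYH7, slow myosin heavy chain, rose to 278 ± 117 FPKM (n = 4, limma adjusted p = 9.09e-06). MYH1, a fast adult form, rose to 19.5 ± 11.2 FPKM from libraries listed at 0 except 1 at 0.0278 FPKM (n = 4, limma adjusted p = 0.000605). All 16 genes of excitation-contraction coupling rose, also when adjusted over the list alone, with a median of 5.44 (camera adjusted p = 2.37e-16, adjusted p = 0.285 with an estimated correlation). ATP2A1, the fast calcium pump, rose from 0.468 ± 0.351 to 327 ± 51.6 FPKM (n = 4, log2 7.82, limma adjusted p = 4.62e-06), and its inhibitor SLN with a log2 fold change of 7.60. Among 9 neuromuscular junction genes 8 rose and 1 fell, also when adjusted over the list alone, with a median of 2.46 (camera adjusted p = 1.89e-05, adjusted p = 0.285 with an estimated correlation). ACHE (log2 4.09) and the acetylcholine receptor subunit CHRND (log2 3.57) rose. The call of UTRN (log2 -0.40, adjusted p = 0.0306) was the only fall of the list and ended under median-ratio scaling (adjusted p = 0.263), quantile normalization (0.118) and without any 1 of 6 of the libraries (adjusted p = 0.0575 to 0.0904). In the dystrophin complex and costamere 8 of 12 members rose, 3 fell and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00618, adjusted p = 0.428 with an estimated correlation), with 1 of the falls left under median-ratio scaling. DMD, dystrophin, rose from 16.5 ± 3.08 to 310 ± 16.3 FPKM (n = 4, log2 4.17, limma adjusted p = 1.58e-05) and SNTB1 by a log2 of 3.82, while TLN2 fell (log2 -1.14). DAG1 fell (log2 -0.57, adjusted p = 0.015), a call that ended under median-ratio scaling (adjusted p = 0.0601), quantile normalization (0.0979) and without undifferentiated male replicate 1 (adjusted p = 0.0504).

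**Figure D2:**
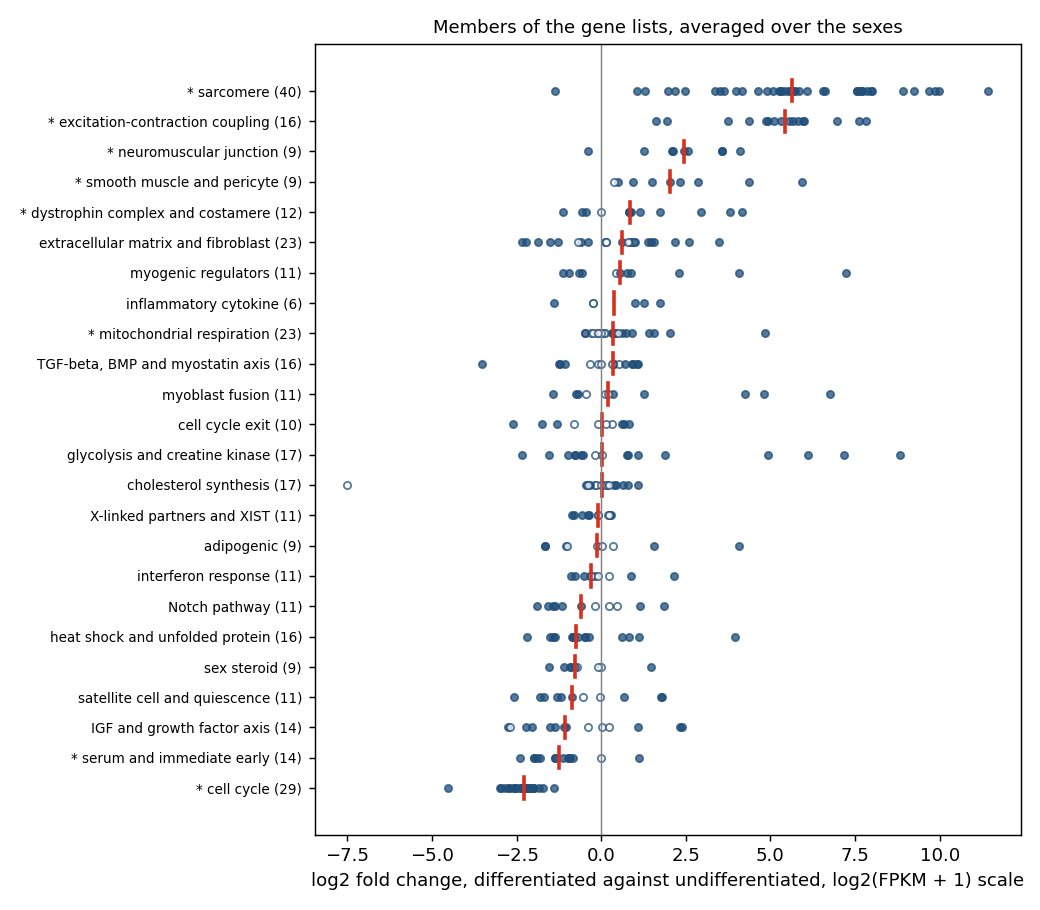
Each point is the log2 fold change of a list member between the states, filled where limma's adjusted p passed, with the list median as a bar and an asterisk where camera's adjusted p was under 0.05. The median was 5.63 for the sarcomere list and -2.28 for the cell cycle list.

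All 29 cell cycle genes fell, also when adjusted over the list alone, with a median of -2.28 (camera adjusted p = 6.06e-09, adjusted p = 0.519 with an estimated correlation). MKI67, a marker of proliferating cells, fell from 33.0 ± 8.37 to 4.48 ± 2.77 FPKM (n = 4, log2 -2.72, limma adjusted p = 0.000598), and CCNA2, cyclin A2, from 42.7 ± 9.01 to 5.11 ± 3.95 FPKM (n = 4, limma adjusted p = 0.000917). In differentiated male replicate 1, 27 of the 29 genes lay above the other 3 differentiated libraries, by a median of 1.22 on the log2 scale, and MKI67 stood at 8.57 FPKM against 2.57, 3.08 and 3.68 FPKM. Among 10 genes of cell cycle exit 3 rose, 3 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.547, adjusted p = 0.806 with an estimated correlation). Its median was 0.02 and its mean -0.40, with the test pointing up. GADD45B (log2 0.81) and RB1 (log2 0.67) rose, and the inhibitors CDKN2B (log2 -2.61) and CDKN2A (log2 -1.75) fell. Of 14 serum and immediate early genes 1 rose, 12 fell and 1 did not pass, also when adjusted over the list alone, with a median of -1.25 (camera adjusted p = 0.00528, adjusted p = 0.285 with an estimated correlation). SRF, a transcription factor of muscle and serum response genes, rose from 10.4 ± 1.04 to 23.6 ± 1.69 FPKM (n = 4, log2 1.12, limma adjusted p = 0.000457), while NR4A1 (log2 -2.39) and IER3 (log2 -1.99) fell.

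Of 17 glycolysis and creatine kinase genes 8 rose, 7 fell and 2 did not pass, also when adjusted over the list alone (camera adjusted p = 0.225, adjusted p = 0.741 with an estimated correlation). Under median-ratio scaling 8 rose and 5 fell. Muscle glycogen phosphorylase, PYGM, rose from 0.381 ± 0.315 to 206 ± 80.4 FPKM (n = 4, limma adjusted p = 2.58e-05). LDHA fell from 624 ± 126 to 124 ± 35.8 FPKM (n = 4, limma adjusted p = 0.000539), and PKM from 1635 ± 183 to 565 ± 67.5 FPKM (n = 4, log2 -1.53, limma adjusted p = 0.000177). Of 23 mitochondrial respiration genes 13 rose, 1 fell and 9 did not pass, also when adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.000999, adjusted p = 0.285 with an estimated correlation). CPT1B, the muscle form of the carnitine transferase, was listed at 0 in 3 undifferentiated libraries and at 0.131 FPKM in the remaining one, and rose to 29.7 ± 9.60 FPKM (n = 4, limma adjusted p = 4.39e-06). SLC25A4 rose (log2 2.02) and HADHA fell (log2 -0.47). Among 9 adipogenic genes 2 rose, 3 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.824, adjusted p = 0.829 with an estimated correlation), with a median of -0.14, a mean of 0.05 and the test pointing up. Without differentiated male replicate 1 that median was 0.12 and 1 member rose. GPD1 (log2 4.07) rose, as did CD36 (log2 1.56), whose call ended with a fixed block by sex and replicate number (adjusted p = 0.0638) and without any 1 of 6 of the libraries (0.0521 to 0.0838). FASN (log2 -1.67) and SCD (log2 -1.65) fell. Of 17 cholesterol synthesis genes 5 rose, 2 fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.311, adjusted p = 0.8 with an estimated correlation). The median was 0.01 and the mean -0.32, with the test pointing up. HMGCS1 (log2 1.09) and FDPS (log2 0.79) rose. The calls of SQLE (log2 -0.44) and SREBF2 (log2 -0.33) ended under median-ratio scaling (adjusted p = 0.207 and 0.2) and quantile normalization (0.178 and 0.0724). That of SQLE also ended with a fixed block by sex and replicate number (adjusted p = 0.0779) and without any 1 library except differentiated male replicate 1 (adjusted p = 0.0519 to 0.104). In differentiated male replicate 1, 15 of these 17 genes lay above the other 3 differentiated libraries, by a median of 0.753 on the log2 scale, and without that library 3 members rose and 3 fell.

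In the IGF axis 3 of 14 members rose, 7 fell and 4 did not pass, 3 and 8 when adjusted over the list alone (camera adjusted p = 0.406, adjusted p = 0.642 with an estimated correlation). The binding proteins split, since IGFBP5 (log2 2.39) and IGFBP3 (log2 2.34) rose while IGFBP2 (log2 -2.75) and IGFBP4 (log2 -2.22) fell. IGFBP2 went from 602 ± 143 to 87.6 ± 18.5 FPKM (n = 4, limma adjusted p = 0.000222). In the TGF-beta, BMP and myostatin axis 7 of 16 members rose, 4 fell and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 0.304, adjusted p = 0.705 with an estimated correlation), with a median of 0.34, a mean of -0.08 and the test pointing up. Without differentiated male replicate 1, 4 members rose. ID1, an inhibitor of myogenic factors, fell from 372 ± 36.7 to 34.8 ± 14.9 FPKM (n = 4, log2 -3.52, limma adjusted p = 0.000672) and SMAD6 also fell (log2 -1.25). ACVR2B rose from 3.48 ± 0.622 to 8.61 ± 2.05 FPKM, and its ligand MSTN, myostatin, from 3.46 ± 0.931 to 8.77 ± 3.99 FPKM (n = 4, limma adjusted p = 0.0378), a call that ended without the filter on low values (adjusted p = 0.0576) and without any 1 of 6 of the libraries (adjusted p = 0.0513 to 0.115). Of 23 extracellular matrix and fibroblast genes 8 rose, 7 fell and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.183, adjusted p = 0.741 with an estimated correlation). Under median-ratio scaling 9 rose and 5 fell. MFAP5 (log2 3.47) and COL1A1 (log2 2.59) rose, and CYR61 (log2 -2.33) and FN1 (log2 -2.22) fell. In differentiated male replicate 1, 18 of the 23 lay above the other 3 differentiated libraries. Of 9 smooth muscle and pericyte genes, 8 rose and 1 did not pass, also when adjusted over the list alone, with a median of 2.03 (camera adjusted p = 2.7e-05, adjusted p = 0.293 with an estimated correlation). ACTA2, smooth muscle actin, rose from 17.9 ± 7.25 to 1091 ± 85.0 FPKM (n = 4, log2 5.94, limma adjusted p = 6.95e-05), and ABCC9 by a log2 of 4.37.

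Camera called none of the heat shock, interferon, inflammatory cytokine and sex steroid lists. Fry called all 4 in either direction, as it did each of the 24 tested lists, so this does not set them apart. In 1 direction fry called those of heat shock (adjusted p = 0.00495), interferon (0.0239) and sex steroid (0.00134). In the heat shock and unfolded protein list 4 of 16 members rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.225, adjusted p = 0.705 with an estimated correlation). Under median-ratio scaling 4 rose and 9 fell. CRYAB, a small chaperone of muscle, rose from 45.0 ± 23.9 to 666 ± 171 FPKM (n = 4, log2 3.95, limma adjusted p = 8.22e-05) and ASNS by a log2 of 1.11, while TRIB3 (log2 -2.19) and ATF4, from 253 ± 15.3 to 87.9 ± 15.5 FPKM (n = 4, limma adjusted p = 0.000392), fell. In the interferon response 2 of 11 rose (IFIT3, log2 2.15, and IFIT2, log2 0.87), 3 fell (among them OAS2, log2 -0.88, and IFIH1, log2 -0.77) and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.766, adjusted p = 0.806 with an estimated correlation). Among 6 inflammatory cytokine genes 3 rose, 1 fell and 2 did not pass, 3 and 2 when adjusted over the list alone or without differentiated male replicate 1 (camera adjusted p = 0.485, adjusted p = 0.705 with an estimated correlation). CCL2 (log2 1.74) and TNFAIP3 (log2 1.27) rose, and LIF fell from 2.66 ± 0.380 FPKM (n = 4) to 1.71, 0, 0.351 and 0 FPKM. The call of CCL2 ended without any 1 of 6 of the libraries (adjusted p = 0.0609 to 0.1), that of LIF without any 1 of 4 (0.0514 to 0.0594) and that of IFIH1 without undifferentiated male replicate 1 (0.0523). Those of CCL2 and IFIH1 also ended with a fixed block by sex and replicate number (adjusted p = 0.0514 and 0.0538). CCL2 stood at 99.0 FPKM in differentiated male replicate 1 against 8.37, 12.8 and 19.5 FPKM in the other differentiated libraries. Of 9 sex steroid genes 1 rose (NCOA1, log2 1.47), 5 fell (SRD5A1, log2 -1.54, and SRD5A3, log2 -1.11, the most) and 3 did not pass, 1 and 6 when adjusted over the list alone (camera adjusted p = 0.225, adjusted p = 0.519 with an estimated correlation). Of 11 X-linked partner genes 1 rose (KDM5C, log2 0.29), 5 fell (CUL4B, log2 -0.87, and EIF2S3, log2 -0.81, the most) and 5 did not pass, 2 and 5 when adjusted over the list alone and 3 and 3 under median-ratio scaling (camera adjusted p = 0.753, adjusted p = 0.822 with an estimated correlation). The KDM5C call ended without any 1 of 5 of the libraries (adjusted p = 0.0539 to 0.0768) and with a fixed block by sex and replicate number (0.0536).

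Few members of the immune, endothelial and Schwann lists were above the filter. Only 1 of the 12 immune genes found was tested, and that was CD14, which fell from 13.4 ± 1.51 to 2.06 ± 0.330 FPKM (n = 4, log2 -2.24, limma adjusted p = 9.12e-05). Of 3 tested endothelial genes 1 fell, also when adjusted over the list alone, and this call of EGFL7 (log2 -0.48) ended under median-ratio scaling (adjusted p = 0.107), quantile normalization (0.0773), a fixed block by sex and replicate number (0.0502) and without any 1 of 5 of the libraries (adjusted p = 0.0512 to 0.0727). The 3 tested Schwann and neural genes all changed, also when adjusted over the list alone. ERBB3 rose from 0.957 ± 0.427 to 64.8 ± 4.14 FPKM (n = 4, log2 5.09, limma adjusted p = 4.11e-06), NES, an intermediate filament also present in regenerating muscle, from 100 ± 4.23 to 440 ± 73.4 FPKM (n = 4, limma adjusted p = 2.91e-05), and S100B fell (log2 -1.02, limma adjusted p = 0.0187), a call that ended without any 1 of 4 of the libraries (adjusted p = 0.0505 to 0.0665). The 2 Y-linked genes tested did not pass in the comparison of states. Camera called 8 lists, 6 up and 2 down, and with an estimated correlation 0 lists, with a lowest adjusted p of 0.285, where fry called 18 in 1 direction.

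Within each sex the same comparison asked whether the state effect held in females and in males. In females 1620 genes rose and 3024 fell, and in males 1674 rose and 2609 fell (limma, Benjamini-Hochberg adjusted). Of these, 1275 rose in both sexes, where independent lists would share 209, and 2114 fell in both, where independent lists would share 609. Both tests used the same estimate of the spread for each gene, so the lists were not independent even without a shared effect. In opposite directions 5 were called. Across genes of at least 300 bp the log2 fold changes of the sexes had a Pearson's r of 0.884 and a Spearman's rho of 0.834, against 0.532 and 0.8 over all tested genes, with genes not independent replicates. ACTA1 rose by a log2 of 11.32 in females and 11.56 in males (n = 2 per group, limma adjusted p = 1.03e-05 and 1.14e-05). In males HUMMLC2B and MYH3 followed (log2 10.99 and 10.08, limma adjusted p = 0.000242 and 6.09e-05). In females ESM1 was among the largest falls (log2 -6.19, limma adjusted p = 0.000384), as was DOK6 (adjusted p = 0.0224). The DOK6 call ended without any 1 of the 4 female libraries (adjusted p = 0.0557 to 0.115). The other symbols named by rule were small RNA genes with extreme values that were listed at 0 in part of the libraries. SNORD58, SNORD53_SNORD92, SNORA42 and SNORA5 were called higher and SNORD16, snoU13 and a 5S_rRNA gene lower in differentiated females. SNORA22 and SNORA42 were called higher and SNORD81, SNORD64, U5, a 5S_rRNA gene and U6 lower in differentiated males. Of these 14 calls, 6 ended without any 1 of 4 to 6 of the libraries. They were those of SNORD58 (adjusted p = 0.0816 to 0.159), SNORD53_SNORD92 (0.0672 to 0.138), SNORA5 (0.0832 to 0.159), SNORA22 (0.0507 to 0.0983), SNORD64 (0.0726 to 0.151) and U5 (0.0938 to 0.111). Without the filter on low values those of SNORD58, SNORD53_SNORD92, SNORA5 and SNORD64 ended (adjusted p = 0.0692, 0.0557, 0.0694 and 0.0557). Those of SNORD58 and SNORA5 ended without a mean-variance trend (0.0568 and 0.057), that of SNORD64 with quantile normalization (0.0577), and those of SNORA5 and U5 with a fixed block by sex and replicate number (0.0517 and 0.0613). Camera called 9 lists in each sex, with 7 up and 2 down, and 0 with an estimated correlation (lowest adjusted p = 0.244 in females and 0.279 in males). Glycolysis and creatine kinase was called up in females (median 0.31, camera adjusted p = 0.0441, adjusted p = 0.661 with an estimated correlation). That call ended under median-ratio scaling (camera adjusted p = 0.0802) and without any 1 of 6 of the libraries. The median of this list was 0.47 without undifferentiated female replicate 1 and 0.15 without undifferentiated female replicate 2. Cholesterol synthesis was called up in males (median 0.46, adjusted p = 0.00173, adjusted p = 0.488 with an estimated correlation). Its median was 0.22 without differentiated male replicate 1 (adjusted p = 0.0322) and 0.77 without differentiated male replicate 2 (adjusted p = 1.06e-05). Without undifferentiated female replicate 1, undifferentiated female replicate 2 or differentiated female replicate 2, the count in females was 2549, 3037 and 2923 in place of 4644. Without undifferentiated male replicate 1, undifferentiated male replicate 2 or differentiated male replicate 2, the count in males was 2381, 2459 and 2677 in place of 4283.

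The comparison of female with male cells, averaged over the states, asked which genes differed by sex. No label says whether each sex held more than 1 animal. Here and in the later comparisons of the sexes, differences outside chromosome Y therefore cannot be told apart from differences between animals. Several of the genes called lower in females lay on the Y chromosome. ENSSSCG00000012178 (chromosome Y, 1277624 to 1297330, no symbol) was listed at 0 in all 4 female libraries and was at 167 ± 55.5 FPKM in males (n = 4, limma adjusted p = 6.97e-06). ENSSSCG00000026430 (chromosome Y, 1115738 to 1132911), a Y-linked gene that the table names DDX3X, was at 0.0434 FPKM in 1 female library, listed at 0 in the other 3, and at 44.4 ± 5.26 FPKM in males (n = 4, log2 -5.48, limma adjusted p = 1.22e-05). UTY was at 13.4 ± 5.42 FPKM and ZFY at 11.9 ± 1.80 FPKM in males (n = 4, limma adjusted p = 0.0089 and 0.000318), both listed at 0 in females. R3HDML (ENSSSCG00000007370, chromosome 17, 52213809 to 52224989) was higher in females, at 6.99 and 6.56 FPKM against 0 and 0 in undifferentiated males, and at 13.7 and 10.8 FPKM against 1.53 and 2.18 FPKM in differentiated males (log2 2.59, limma adjusted p = 0.00295).

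Of 12963 genes, 3 were higher and 8 lower in females (limma, Benjamini-Hochberg adjusted), with 1261 at an unadjusted p under 0.05. The genes without a symbol were chosen after their values were seen. The Y-linked ENSSSCG00000027046 and ENSSSCG00000029864 were at 28.1 ± 2.23 and 27.4 ± 4.31 FPKM in males (n = 4) and listed at 0 in females (limma adjusted p = 3.08e-05 and 0.000128). ENSSSCG00000024349 (scaffold GL895979.2, 17236 to 32322) was at 7.53 and 6.00 FPKM in undifferentiated and 30.3 and 34.2 FPKM in differentiated males, against 0, 0, 1.98 and 1.68 FPKM in females (limma adjusted p = 0.000405). ENSSSCG00000030068 (chromosome 1, 202365116 to 202366927) was at 15.9 and 15.7 FPKM in undifferentiated females and listed at 0 elsewhere (limma adjusted p = 0.037), a call that ended with a pseudocount of 0.1 (adjusted p = 0.375) and without any 1 of the 4 undifferentiated libraries (0.0555 to 0.129). It also ended with replicate number as a block (adjusted p = 0.148) and with a random block by sex and replicate number (0.0521). A U6 gene of 106 bp had values of 2086000 and 414800 FPKM in undifferentiated males alone, and ENSSSCG00000026167, of 153 bp, had 3893 and 1730 FPKM in undifferentiated females alone, with all other libraries listed at 0. Of 13 genes on chromosome Y, 8 were tested, and all 8 were above 0 in all 4 male libraries while 7 were at 0 in all females. The call of UTY ended without any 1 of the 4 differentiated libraries (adjusted p = 0.0637 and 0.0647 without female replicate 1 or 2, and 0.0644 and 0.0542 without male replicate 1 or 2). The count of 11 became 28, 32, 28, 20, 17, 21 and 26 without undifferentiated female replicate 1 or 2, undifferentiated male replicate 1, differentiated female replicate 1 or 2, or differentiated male replicate 1 or 2.

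**Figure D3:**
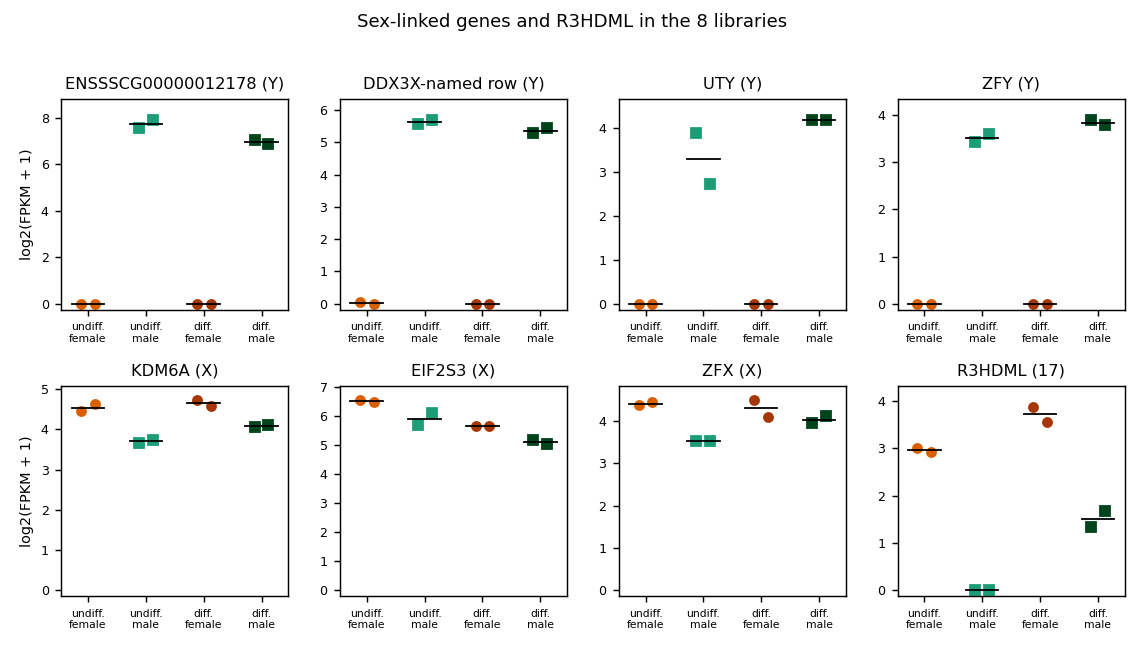
Points show log2(FPKM + 1) of 4 genes on chromosome Y, 3 X-linked partners and R3HDML in the 8 libraries, by state and sex, with bars at the mean of each group of 2. The 4 genes on chromosome Y were above 0 in all 4 male libraries, and only the DDX3X-named gene was above 0 in a female library, at 0.0434 FPKM.

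Among 11 X-linked partners of Y-linked genes 0 passed over all genes, and 4 were higher in females when adjusted over the list alone. The list was called up in females with a median of 0.27 (camera adjusted p = 0.00152, adjusted p = 0.584 with an estimated correlation), which was 0.16 without undifferentiated male replicate 2. KDM6A was at 20.7, 23.8, 25.6 and 22.9 FPKM in females against 11.7, 12.2, 15.7 and 16.1 FPKM in males (log2 0.71, limma adjusted p = 0.147). EIF2S3 (log2 0.58, limma adjusted p = 0.320) and ZFX (log2 0.57, limma adjusted p = 0.321) had values of the same sign, while CUL4B (log2 -0.38) and KDM5C (log2 -0.09) had the opposite sign. Sarcomere genes were called up in females with a median of 0.32 (camera adjusted p = 2.57e-10, adjusted p = 0.584 with an estimated correlation), with 0 of 40 members past the threshold over all genes and 3 adjusted over the list alone. Without undifferentiated female replicate 2 that median was 0.16 (adjusted p = 3.31e-05). Excitation-contraction coupling was called up with a median of 0.23 (camera adjusted p = 1.62e-05, adjusted p = 0.584 with an estimated correlation), with 0 of 16 members past the threshold either way. Its median was 0.36 without undifferentiated female replicate 1 and 0.15 without undifferentiated female replicate 2. Extracellular matrix and fibroblast genes were called down in females with a median of -0.57 (camera adjusted p = 3.71e-05, adjusted p = 0.584 with an estimated correlation), with 0 of 23 past the threshold over all genes, and 2 higher and 13 lower when adjusted over the list alone. COL1A1 was at 34.7, 22.0, 165 and 178 FPKM in females and 179, 58.5, 783 and 500 FPKM in males (log2 -1.86, limma adjusted p = 0.326). DCN, decorin, was at 0.999, 1.42, 1.18 and 4.20 FPKM in females and 4.46, 5.86, 21.3 and 6.38 FPKM in males (log2 -1.70, limma adjusted p = 0.419). Cell cycle genes were called down in females with a median of -0.45 (camera adjusted p = 5.13e-05, adjusted p = 0.761 with an estimated correlation), with 0 of 29 past the threshold either way. Without differentiated male replicate 1, highest of the differentiated libraries in 27 of the 29, that median was -0.21 and the call ended (adjusted p = 0.053), and without differentiated male replicate 2 the median was -0.73. The matrix list without differentiated male replicate 1 had an adjusted p of 0.00147. The other 19 tested lists had camera adjusted p between 0.0713 and 0.986. Among them, the sex steroid list had a median of -0.10 with the test pointing up (adjusted p = 0.627), and 0 of its 9 members passed. Fry called 0 lists in 1 direction and 9 in either direction.

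**Figure D4:**
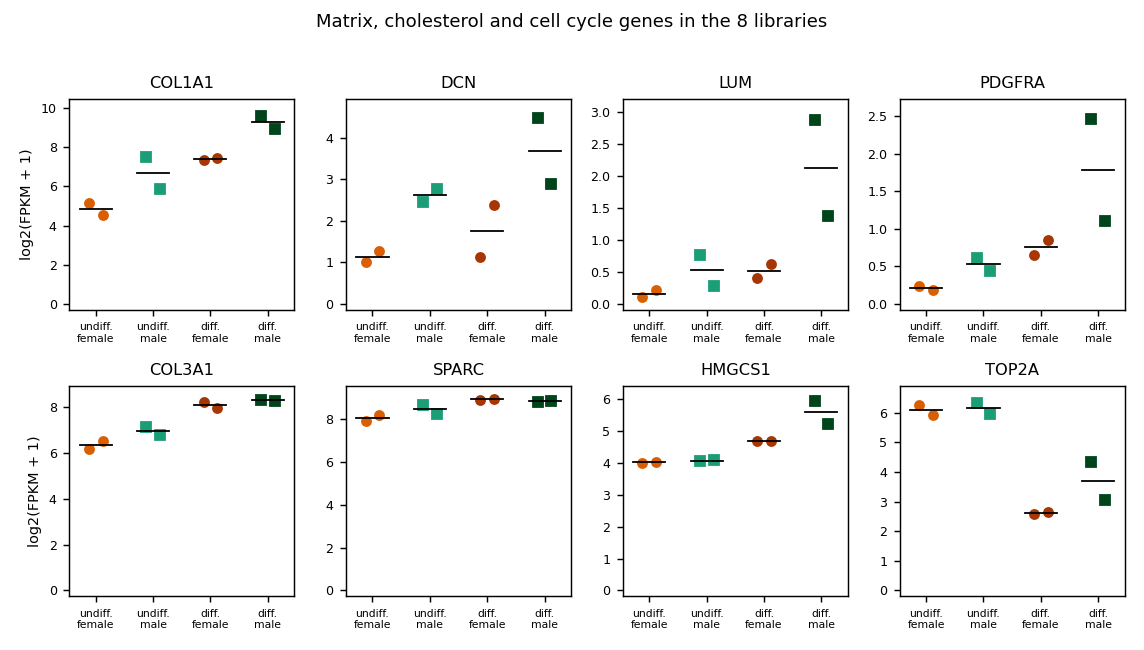
Points show log2(FPKM + 1) of COL1A1, DCN, LUM, PDGFRA, COL3A1, SPARC, HMGCS1 and TOP2A in the 8 libraries, by state and sex, with bars at the mean of each group of 2. DCN reached 21.3 FPKM in differentiated male replicate 1, while SPARC lay between 435 and 490 FPKM in all 4 differentiated libraries.

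Within undifferentiated cells 4 genes were higher and 8 lower in females (limma, Benjamini-Hochberg adjusted), with 542 at an unadjusted p under 0.05. R3HDML (adjusted p = 0.00856, but 0.0618 to 0.0721 without undifferentiated female replicate 1 or 2 or male replicate 2), the DDX3X-named Y-linked gene (8.83e-05) and ZFY (0.00241) were again called. The R3HDML and ZFY calls ended with a filter at a mean of 5 FPKM (adjusted p = 0.111 and 0.108), and with only the groups compared 0 genes were called. ENSSSCG00000021945 (chromosome 15, 20364870 to 20366019), chosen after its values were seen, was at 23.4 and 45.5 FPKM in undifferentiated females, listed at 0 in undifferentiated males, and at 44.8 to 73.1 FPKM in differentiated cells (limma adjusted p = 0.00532, but 0.0721 without undifferentiated male replicate 2). In differentiated cells 0 genes were higher and 6 lower in females, with 1611 at an unadjusted p under 0.05, and 5 of the 6 lay on chromosome Y. The ZFY call there ended with the filter at 5 FPKM (adjusted p = 0.0937) and with only the groups compared (0.0515), as did that of ENSSSCG00000024349 in the latter (0.0638). Sarcomere genes were called up in females in both states, with medians of 0.28 and 0.41 in undifferentiated and differentiated cells (camera adjusted p = 4.26e-05 and 1.84e-07, lowest adjusted p = 0.690 and 0.782 of any list with an estimated correlation). In undifferentiated cells that call ended without female replicate 2 (median -0.04). That library lay above the others in ACTA1, CKM and MYH7, at low log2(FPKM + 1) values of 1.19, 0.166 and 0.504. The median was 0.65 without female replicate 1 and 0.15 without male replicate 2. In differentiated cells it was 0.33 without male replicate 1, the lowest differentiated library in 22 of the 40 genes. Excitation-contraction coupling was also called up in both (adjusted p = 0.00339 and 0.000684, with 0.696 and 0.782 under an estimated correlation). These calls ended without female replicate 2 of the state (adjusted p = 0.53 and 0.11) and, in undifferentiated cells, without male replicate 1 (0.0758). In differentiated cells the median of 0.31 was 0.50 without female replicate 1 and 0.18 (adjusted p = 0.0305) without male replicate 1, the lowest differentiated library in 10 of the 16 genes. The matrix list was called down in both (medians -0.41 and -0.67, adjusted p = 0.00336 and 0.000156, with 0.696 and 0.782 under an estimated correlation). In undifferentiated cells this call ended without female replicate 2 or male replicate 1 (adjusted p = 0.11 and 0.119), and in differentiated cells the median was -1.01 without male replicate 2 and -0.45 (adjusted p = 0.0305) without male replicate 1. X-linked partners were called up in undifferentiated cells (median 0.41, adjusted p = 4.26e-05, adjusted p = 0.690 with an estimated correlation). In differentiated cells the cell cycle list was called down (median -0.78, adjusted p = 6.32e-05, adjusted p = 0.782 with an estimated correlation), a call that ended without differentiated male replicate 1 (median -0.16, adjusted p = 0.41). Glycolysis and creatine kinase (median 0.25, adjusted p = 0.00575) and mitochondrial respiration (median 0.19, adjusted p = 0.00287) were called up there, both with an adjusted p = 0.782 under an estimated correlation. Without differentiated female replicate 2 both calls ended, with medians of -0.04 and 0.12 (adjusted p = 0.744 and 0.123), and without male replicate 2 with medians of 0.25 and 0.08 (0.22 and 0.114). The glycolysis median was 0.39 without female replicate 1. Cholesterol synthesis was called up in undifferentiated (median 0.22, adjusted p = 4.41e-05, adjusted p = 0.696 with an estimated correlation) and down in differentiated females (median -0.50, adjusted p = 2.03e-05, adjusted p = 0.782 with an estimated correlation). The medians were 0.36 without undifferentiated female replicate 2, 0.34 without undifferentiated male replicate 1, and in differentiated cells -0.77 without male replicate 2 and -0.37 (adjusted p = 0.00388) without male replicate 1, the highest differentiated library in 15 of the 17 genes. In differentiated cells 0 of the 17 cholesterol genes passed over all genes and 8 were lower when adjusted over the list alone. The count of 12 in undifferentiated cells became 32, 27 and 32 without undifferentiated female replicate 1 or 2 or undifferentiated male replicate 1. The count of 6 in differentiated cells was between 10 and 22 with any 1 of the 8 libraries left out, and 22 without differentiated male replicate 1 or 2.

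The difference of the differentiation effect between the sexes was called for 3 genes, 2 larger and 1 smaller in females (limma, Benjamini-Hochberg adjusted), with 782 at an unadjusted p under 0.05. A gene chosen after its values were seen, ENSSSCG00000026076 (chromosome 2, 95590522 to 95592985), went from 10.1 and 10.1 to 40.8 and 48.1 FPKM in females and from 60.3 and 72.9 to 22.3 and 15.9 FPKM in males (log2 difference 3.79, limma adjusted p = 0.0355). Its call ended with replicate number as a block (adjusted p = 0.152), with a fixed block by sex and replicate number (0.401), under median-ratio scaling (0.057) and without any 1 of 5 of the libraries (0.0603 to 0.0981). U6 and ENSSSCG00000026167 were the others, each above 0 in 1 group alone, and both calls ended with the fixed block (adjusted p = 0.055). The count was 19, 25, 19, 7, 10, 8, 13 and 11 with each library left out, in the order undifferentiated female, undifferentiated male, differentiated female and differentiated male, replicates 1 and 2 of each. Of 24 lists 4 were called by camera and 0 with an estimated correlation (lowest adjusted p = 0.855). Cholesterol synthesis had a median difference of -0.83 (adjusted p = 1.4e-09, adjusted p = 0.855 with an estimated correlation), with 0 of 17 members past the threshold over all genes and 7 adjusted over the list alone. Without differentiated male replicate 1 that median was -0.59 (adjusted p = 1.35e-06). HMGCS1, at the head of that pathway, was at 14.9, 15.3, 15.5 and 16.0 FPKM in the undifferentiated libraries, at 24.4 and 24.8 FPKM in differentiated females and at 60.3 and 35.9 FPKM in differentiated males. Glycolysis and creatine kinase (0.39, adjusted p = 0.000235) and mitochondrial respiration (0.22, adjusted p = 0.0118) had larger effects in females, both with an adjusted p = 0.855 under an estimated correlation. Both calls ended without differentiated female replicate 2, with medians of 0.10 and 0.10 (adjusted p = 0.218 and 0.22), and that of respiration also without undifferentiated female replicate 1 (0.0612) or differentiated male replicate 2 (0.0996). The cell cycle list had a median of -0.57 (adjusted p = 0.0266, adjusted p = 0.855 with an estimated correlation), which was 0.02 without differentiated male replicate 1 (adjusted p = 0.955). The call also ended without undifferentiated female replicate 1 (adjusted p = 0.387), undifferentiated male replicate 2 (0.963) or either differentiated female (0.13 and 0.138).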

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

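The tests of explanations in this part were chosen after the result was seen. The gene tests of the difference between the sexes and the tests of libraries far from the others were planned. List tests of that difference were not among the planned ones. A gap of 1 library to the nearest of the other 3 in its state, divided by the range, marked a far library above Dixon's critical value of 0.829. Of 100 groups tested, 7 passed, and chance alone gives about 5% if values are normally distributed. With 3 libraries listed at 0 and 1 above, as in CKM, MYH1 and DOK6, the ratio is 1 whatever the value. The 7 therefore cannot be weighed against that 5%.

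Undifferentiated female replicate 2 stood above the other undifferentiated libraries in ACTA1 (ratio 0.905, log2 value 1.19 against 0.503 to 0.568), in CKM (ratio 1, 0.166 against 0) and in MYH7 (ratio 0.925, 0.504 against 0 to 0.0379). In KLHL31, differentiated female replicate 2 stood above the others (ratio 0.869, 8.90 against 8.23 to 8.32). In MYH1, undifferentiated male replicate 1 was at 0.04 on the log2 scale with the others listed at 0 (ratio 1). The mean of the sex steroid list was lowest in undifferentiated male replicate 2 (ratio 0.847, 4.19 against 4.42 to 4.46). For DOK6, differentiated male replicate 1 was at 3.91 with the others listed at 0 (ratio 1).

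The effect of differentiation differed between the sexes, by limma's test of the difference, for ENSSSCG00000026076 (log2 difference 3.79, adjusted p = 0.0355), U6 (19.83, adjusted p = 0.00451) and ENSSSCG00000026167 (-11.34, adjusted p = 0.00451). U6 and ENSSSCG00000026167 span 106 and 153 bp and were above 0 in 1 group alone, so that their differences depend on the pseudocount. With a fixed block by sex and replicate number none of the 3 calls held (adjusted p = 0.401 for ENSSSCG00000026076 and 0.055 for the others). By camera it differed for cholesterol synthesis (median -0.83, adjusted p = 1.4e-09), glycolysis and creatine kinase (0.39, adjusted p = 0.000235), mitochondrial respiration (0.22, adjusted p = 0.0118) and the cell cycle (-0.57, adjusted p = 0.0266). None of these 4 calls held with an estimated correlation (adjusted p = 0.855 for each). Without differentiated male replicate 1 the cell cycle median was 0.02 (adjusted p = 0.955), and without differentiated female replicate 2 those of glycolysis and respiration were both 0.10 (adjusted p = 0.218 and 0.22).

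Differentiated male replicate 1 lay above the other 3 differentiated libraries in 27 of 29 cell cycle, 15 of 17 cholesterol synthesis and 18 of 23 matrix genes, and was lowest in 22 of 40 sarcomere genes. Undifferentiated cells left in that culture would need a share of 19.9% for the cell cycle genes (quartiles 17.3 to 28.2). For 60 abundant genes that fell, the median was 6.68% (quartiles -0.154 to 15.8). These were called with a log2 fold change below -2 and a mean of at least 100 FPKM in undifferentiated cells. That selection included differentiated male replicate 1 and so favours genes low in it. The cell cycle list was examined because it was high there. The gap therefore cannot decide on such cells. For cholesterol synthesis, 12 of the 17 genes lay above every undifferentiated library, by a median of 0.228 on the log2 scale over all 17. Leftover cells with the profile of the undifferentiated cultures would not give this. This argument, like the shares above, assumes that such cells kept that profile in the differentiated culture, which was not tested. More fibroblasts in that culture cannot be told apart from a change within the muscle cells, because the 5 most abundant matrix genes lay between -0.57 (MFAP5) and 1.67 (COL1A1) with a median of 0.144 and muscle cells also express them. A difference between cultures or animals stays open and untested, since the labels give neither and differentiated male replicate 2 is the only other library of its group.

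Values above 100000 FPKM were found in 218 genes, and 98.2% of these spanned under 300 bp against 12.3% of the table, which is consistent with genes shorter than a sequenced fragment as the source. The 4 longer genes, with a smallest span of 331 bp, were 7SK (70218 to 131239 FPKM in all libraries), HSBP1 (642211, 0, 305661 and 61169 FPKM in undifferentiated and 0 in differentiated libraries), H-FABP (273279 FPKM in differentiated male replicate 1 and 0 elsewhere) and MRC2 (130536 FPKM there and 3.67 to 11.1 FPKM elsewhere). A short transcript within these 4 genes stays open, because the transcript models behind the values were not used here. No biological explanation of these values above 100000 FPKM was tested.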

How the results depend on the processing

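Tests without genes that span under 300 bp, and of called lists within a sex or a state and for the difference of the effect with each library left out, were chosen after the result was seen, and the other settings were planned. The states averaged over the sexes gave 6476 genes, and between 5292 and 6840 under the other settings, each with more falls than rises except median-ratio scaling (3128 rises and 3008 falls). With replicate number as a block, 2313 genes rose and 4129 fell. Replicate numbers were not taken as pairs, because no label says that equal numbers belong together. Deviations of replicate 1 from its group mean correlated between groups at -0.0411 to 0.131 across genes. Between the states of 1 sex the correlation was 0.113 in females and 0.126 in males, so pairing within a sex stays open. The correlation within sex and replicate number was 0.119. With each library left out, the count was 5217 to 5991 for the states averaged over the sexes, 2549 to 4608 in females and 2381 to 4052 in males. It was 15 to 32 for the sexes averaged over the states, 14 to 32 in undifferentiated and 10 to 22 in differentiated cells, and 7 to 25 for the difference of the effect. A lone library is assumed to vary like the other groups. These fits have fewer samples, and the cause of the higher counts between the sexes was not tested. The number of called lists was then 8 to 9 for the states and 5 to 8 for the sexes, with 8 without differentiated male replicate 2. For the difference of the effect, the cell cycle median of -0.57 was 0.0151 without differentiated male replicate 1 and -1.08 without differentiated male replicate 2, a library of the same group.

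For the sexes in differentiated cells the count of 6 became 13 with a pseudocount of 0.1, 42 without a filter, 13 with quantile normalization, 10 with median-ratio scaling, 13 without a mean-variance trend, 12 with only the groups compared and 12 without genes under 300 bp. The count of 3 for the difference of the effect became 6 without a filter, 7 with quantile normalization, 6 without a trend and 0 with a fixed block by sex and replicate number (limma, 831 at an unadjusted p under 0.05). With only the groups compared, the count in males was 2660 and the count between the sexes in undifferentiated cells was 0 (limma, 702 at an unadjusted p under 0.05), fits with fewer samples. For the other changes the cause was not tested. Of the lists, 8 were called for the states, against 0 with an estimated correlation, 18 by fry in 1 direction and 24 in either direction. For the sexes 5 were called, against 0 with an estimated correlation, 0 by fry in 1 direction and 9 in either direction. Unlike camera, fry does not compare a list with other genes.

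The 172 named values were compared 1858 times with other settings, of which 1803 kept their direction and side of the threshold, 55 lost the call and 0 turned. With each library left out, 1253 of 1376 kept both, 122 lost the call, 1 gained it and 0 turned. A comparison of read counts was not run because whole reads were not recovered. Lists were not run with the random block, which camera does not take, and the sex comparisons could not be fitted with the fixed block by sex. The unknown depth limits what can be said of genes listed at 0.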

Other observations

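The gene families, the tests of explanations and the splits in this part were chosen after the result was seen. Of 68 tested cytosolic ribosomal protein genes 0 rose, 61 fell and 7 did not pass, with a median log2 fold change of -0.80, or -0.62 relative to all genes. Under median-ratio scaling 55 fell (camera adjusted p = 2.26e-12 over the families, adjusted p = 0.297 with an estimated correlation). RPS18 fell from 3448 ± 228 to 1328 ± 160 FPKM (n = 4, log2 -1.38, limma adjusted p = 0.000395) and RPL13 from 705 ± 34.4 to 296 ± 28 FPKM (n = 4, log2 -1.25, limma adjusted p = 0.000121). RPL38 was at 591 ± 21.1 and 507 ± 81.5 FPKM (n = 4, limma adjusted p = 0.118). Of 25 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 1 rose, 13 fell and 11 did not pass, with 11 falls under median-ratio scaling (camera adjusted p = 0.0094, adjusted p = 0.297 with an estimated correlation). GARS fell from 231 ± 28.3 to 52.6 ± 24.1 FPKM (n = 4, limma adjusted p = 0.000598). RARS2, the mitochondrial arginine form, rose from 10.4 ± 0.697 to 15.7 ± 0.429 FPKM (n = 4, log2 0.55, limma adjusted p = 0.00335). Of 6 chaperonin genes, which fold actin and tubulin, 5 fell, and 4 under median-ratio scaling (camera adjusted p = 0.045, adjusted p = 0.452 with an estimated correlation). Of 25 RNA polymerase subunit genes 8 fell and 17 did not pass, with 1 rise and 3 falls under median-ratio scaling (camera adjusted p = 0.105, adjusted p = 0.452 with an estimated correlation).

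Of 15 clustered histone genes 0 rose, 12 fell and 3 did not pass, with the same counts under median-ratio scaling and a median of -2.49 (camera adjusted p = 0.000194, adjusted p = 0.297 with an estimated correlation). HIST1H2AD fell from 490 ± 83.4 to 57.1 ± 30.6 FPKM (n = 4, log2 -3.20, limma adjusted p = 0.000759) and HIST1H1B from 218 ± 51.9 to 24.2 ± 7.23 FPKM (n = 4, log2 -3.13, limma adjusted p = 0.000258). How reads were shared among near-identical copies of histone and ribosomal genes is unknown. Of 33 complex I genes 19 rose, 0 fell and 14 did not pass, with 24 rises under median-ratio scaling (median 0.40, camera adjusted p = 7.09e-06, adjusted p = 0.297 with an estimated correlation). NDUFA8 rose from 40.2 ± 3.21 to 101 ± 20 FPKM (n = 4, log2 1.29, limma adjusted p = 0.000224). Mitochondrial ribosomal genes went both ways, with 4 rises and 18 falls of 64 as deposited but 9 rises and 6 falls under median-ratio scaling (camera adjusted p = 0.222, adjusted p = 0.452 with an estimated correlation). Of 34 proteasome genes 8 rose and 4 fell, against 17 and 1 under median-ratio scaling (camera adjusted p = 0.105, adjusted p = 0.452 with an estimated correlation).

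More genes fell than rose in differentiated cells, with a median of -0.18 over all genes. Very short genes made 360 of the 12963 tested, and 63.8% of the calls fell without them. Their own calls thus do not account for the excess, but they were too few to move that share much. The lower depth of differentiated libraries is argued against as the cause. Among genes with a mean of at least 50 FPKM, 63.8% of the calls also fell (748 of 1173). A larger part of the sum taken by muscle transcripts cannot be told apart from other causes. Without genes above 100000 FPKM or under 300 bp, the sarcomere list held 0.226% to 0.399% of the summed FPKM in undifferentiated libraries. In differentiated libraries it held 8.2% to 11%. This predicts a shift of -0.139 for all other genes if the sum stays fixed. But the sum itself differed between the states by a log2 of -0.185 (511602 to 659592 FPKM). The list leaves out other muscle transcripts such as HUMMLC2B, and a share of summed FPKM is not a share of fragments. The shift due to all muscle transcripts is thus unknown. Total RNA in the cells was not measured, and values scaled to the mapped fragments cannot show whether it fell. Under median-ratio scaling 3128 genes rose and 3008 fell, so the excess of falls depends on the scaling.

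The list of X-linked partners of Y-linked genes was called up in females averaged over the states (median 0.27, camera adjusted p = 0.00152, adjusted p = 0.584 with an estimated correlation), with 0 of 11 members past the threshold over all genes. In differentiated cells it was not called (median 0.10, camera adjusted p = 0.219, adjusted p = 0.782 with an estimated correlation). A shift of the whole X chromosome might lie behind the list's call. The median female against male difference was -0.02 for 420 X-linked and -0.03 for 11166 autosomal genes, a difference of 0.00967, which argues against this. The 8 libraries can be split into 4 and 4 in 34 ways, the real one included, once the split by the other factor is set aside. In a model of state and sex without their interaction, only 1 split, the real one, gave as many calls for the states (6570, highest other 4). Every other split leaves the state effect in the residual spread, so few calls there were bound to follow. With 34 splits, this comparison alone cannot exclude chance. For the sexes 2 splits gave as many calls, the real one included (8, highest other 9). Chance cannot be excluded for that number of calls, which does not weigh which genes were called. Of 8 tested genes on chromosome Y, 7 were at 0 in all females, and all 8 were above 0 in all males. This argues against chance for those genes.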
